A study of Rattus norvegicus with 6 samples.

How the data were processed

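Messenger RNA of neonatal rat ventricular cardiomyocytes, heart muscle cells isolated from newborn rats and kept in culture, was sequenced in 6 libraries. The titles put 3 libraries in a group named Bgal and 3 in a group named Trim28. Per the series' design text, cells were infected with an adenovirus that expresses TRIM28. The labels neither expand the name Bgal nor say which virus the cells of that group received, and give no dose, time or batch. Per the labels' protocols, poly(A) RNA was selected, the second DNA strand was marked with dUTP and removed before amplification, and the libraries were read in pairs on an Illumina instrument.

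The deposited table holds FPKM values per the file headers, which are fragments scaled by gene length and by the library total, for 34510 genes in 1 column per library, with no pooling. Per the submitters' processing notes, HISAT2 2.0.5 and DESeq2 were used by the authors. The counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here. Gene coordinates, gene lengths, gene classes and transcription factor families are those of the deposited table, per the file headers, with Ensembl rat gene identifiers. The table had 0 columns of other samples.

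FPKM divides by gene length and by the library's total, so a gene that takes many reads lowers the values of all others, and short genes carry few reads per unit of FPKM. The product of FPKM and gene length was a whole multiple of 1 step per library for 100% of the values above 0, within 0.01 of a whole number. Those steps gave the reads of each gene. Reads assigned to genes were 34593292, 28574951 and 34202760 in Bgal libraries 1 to 3 and 27789223, 26146166 and 28298731 in Trim28 libraries 1 to 3. One read on a gene of 1 kilobase corresponded to between 0.0281 and 0.0381 FPKM. What the deposited pipeline counted as 1 read, a fragment or a mate, is not given in the sources used here. Over the 1575 genes with 1 to 20 reads in every library, odd read counts made up 39.2% ± 2.11 of the Bgal values and 44.1% ± 1.04 of the Trim28 values (mean ± SD of 3 libraries, exact permutation p = 0.1, the smallest that 3 against 3 allows). The cause of this difference was not tested.

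The design fixed before the data were examined assumed counts, with a limma test on log2 values as the written fallback for normalised values. Because the table held FPKM, the fallback was used. Genes with at least 0.5 FPKM in at least 3 libraries were tested, which left 14808 genes. Values were transformed to log2(FPKM + 1) and compared between the groups with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance and Benjamini-Hochberg adjustment over the 14808 genes. Each fold change on the log2 scale is of FPKM + 1, which understates the change of genes with low values, while folds without that wording are ratios of mean FPKM. The threshold was an adjusted p of 0.05. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.53 to 17 over genes with at least 50 reads, so none was a copy of another library of its group. Each was counted as 1 replicate as labelled, and this does not show that the cultures were separate. Values are given as mean ± SD of the 3 libraries of a group. Every test was two-sided.

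Before the data were examined, 23 gene lists were fixed: iron handling, suppressors and drivers of ferroptosis, NRF2 targets, contractile genes, the fetal and stress program, fibroblast and matrix genes, smooth muscle and mural cell markers, endothelial markers, leukocyte and macrophage markers, interferon response, inflammatory response, glycolysis and hypoxia, fatty acid oxidation, respiratory chain, cell cycle, p53 targets, ATF4 targets, endoplasmic reticulum stress, heat shock, cholesterol synthesis, TRIM28 partners and imprinted genes. Some genes stand in more than 1 list, such as Cisd1, Tfrc, Hmox1, Ptgs2, Il6 and Myh7. The lists held 426 distinct symbols, of which 405 were found in the table and 376 were tested. Lists with at least 5 tested members were compared with all other tested genes by camera of limma, with a preset correlation between genes of 0.01 and adjustment over the 23 lists. Camera with a correlation estimated for each list, and fry, were alternatives.

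The genes named in the text follow a rule also fixed beforehand. It took Trim28, Tfrc and Ireb2, then Gpx4, Acsl4, Slc7a11, Fth1 and Slc40a1 whatever their result. It added the 8 genes with the largest rise and the 8 with the largest fall in log2 fold change among genes past the threshold, with at least 1 FPKM in the higher group and no overlap between the groups. Genes without a symbol or with a placeholder symbol were passed over. Of each list, it took up to 4 members with the smallest p-values. Some genes that the rule took are not reported here.

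The limma and camera steps were tested on simulated reads for this comparison, drawn for the 14808 genes from the means of the Bgal libraries and the real library sizes. The changed genes were taken only from genes above a minimum of expected reads in the smallest library. All 100 genes changed 2-fold and 78 of 100 genes changed 1.5-fold were recovered, with 9 false calls. Of 20 lists without a shift 0 were called, and 2 of 2 shifted lists were called. The simulated genes were drawn independently with a common dispersion of 0.00424, and the shifted lists held genes changed 2-fold. Estimated correlations in the real lists reached 0.743, in the interferon list. The simulation therefore does not test camera on lists of correlated genes or on smaller shifts. Nor does it test the recovery of changed genes with few reads.

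The alternatives fixed beforehand were median-of-ratios scaling, library totals without Trim28, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, a required fold change of 2, a pseudocount of 0.1 in place of 1, and each library left out in turn. A DESeq2 fit had been planned for counts only and was not run, since the deposited values are FPKM. Alternatives chosen after seeing the data were limma-voom on the recovered reads, removal of each library's trend with gene length by a loess curve of span 0.3, and protein-coding genes alone.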

Results

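The series asks what adenoviral expression of TRIM28, a corepressor that works with zinc finger proteins on chromatin, does to the transcripts of neonatal rat ventricular cardiomyocytes. The series frames this around ferroptosis, a form of cell death driven by iron and lipid peroxidation, and around the iron regulatory protein IRP2 and the transferrin receptor. Gene expression was measured by poly(A) RNA sequencing in 3 Bgal and 3 Trim28 libraries. Reads assigned to genes ranged from 26146166 in Trim28 replicate 2 to 34593292 in Bgal replicate 1, and between 19230 and 20049 genes had a value above 0. Within the groups, log2 values correlated at 0.986 to 0.989 on average per library, and between the groups at 0.966 to 0.970. The labels do not say that the libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

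Trim28 itself (ENSRNOG00000027487, chromosome 1, 65544373 to 65551043, minus strand) was given first as a check of the labels. Its level rose from 82.3 ± 5.16 FPKM in the Bgal libraries to 2264 ± 1112 FPKM in the Trim28 libraries (SD, n = 3 each), which is 27.5-fold. The log2 change was 4.60 with an SE of 0.39 and a limma adjusted p of 0.000193. The 3 Trim28 libraries differed among themselves, with 2923, 2890 and 980 FPKM. Trim28 took 0.871%, 0.861% and 0.295% of the gene reads in these libraries, against 0.0231% to 0.0265% in the Bgal libraries. Coordinates are those of the deposited table, and the genome build is not given in the sources used here.

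Tfrc, the transferrin receptor that brings iron into cells (ENSRNOG00000001766, chromosome 11, 71397383 to 71419223), fell from 139.6 ± 8.92 to 112 ± 2.79 FPKM (SD, n = 3 each). Its log2 change was -0.32 with an SE of 0.05, a 95% confidence interval of -0.45 to -0.19 and a limma adjusted p of 0.00311. Ireb2, which encodes IRP2 (ENSRNOG00000013271, chromosome 8, 59420123 to 59501118), stood at 30.1 ± 0.685 and 28.6 ± 0.763 FPKM. Its log2 difference of -0.07 did not pass (95% confidence interval -0.18 to 0.04, limma adjusted p = 0.258). Scd, a fatty acid desaturase that makes monounsaturated lipids, fell 2.46-fold, from 33.7 ± 3.26 to 13.7 ± 0.676 FPKM.

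Of 19 tested iron handling genes, 3 rose, 6 fell and 10 did not pass, with the same counts adjusted over the list alone. Slc39a8, a metal ion transporter, rose from 2.73 ± 0.303 to 5.40 ± 0.504 FPKM, and the iron-sulfur cluster scaffold gene Iscu from 110.1 ± 4.99 to 136 ± 4.74 FPKM. Ftl1, the ferritin light chain gene, also rose, from 343 ± 9.02 to 436 ± 28.8 FPKM (limma adjusted p = 0.0028), and was chosen here after its values were seen. Cisd1, an iron-sulfur protein of the outer mitochondrial membrane, fell from 172 ± 6.98 to 135 ± 2.58 FPKM, and Hamp, which encodes the iron hormone hepcidin, from 69.2 ± 9.34 to 41.1 ± 5.48 FPKM. The list as a whole did not pass in camera (median log2 change -0.08, adjusted p = 0.654, and adjusted p = 0.708 with an estimated correlation).

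Among 17 tested ferroptosis suppressors, 2 rose and 6 fell, or 5 and 6 adjusted over the list alone. Scd, Nfe2l2, Cisd1 and Gclm fell. The 2 that rose were Gclc and Slc3a2. Slc3a2, chosen here after its values were seen, went from 101 ± 4.75 to 129 ± 9.80 FPKM (limma adjusted p = 0.00468). Nfe2l2, the gene of the antioxidant transcription factor NRF2, went from 102 ± 4.11 to 73.2 ± 4.21 FPKM, and Gclm, a subunit of the enzyme that starts glutathione synthesis, from 31.6 ± 2.38 to 21.9 ± 1.17 FPKM. Camera did not pass for this list (adjusted p = 0.708). Its median log2 change of 0.08 was positive, while its mean of -0.08 and the direction of the test were negative. Slc7a11, the cystine transporter that feeds glutathione synthesis, stood at 1.31 ± 0.161 and 1.81 ± 0.0758 FPKM (log2 difference 0.28, limma adjusted p = 0.0601). Its call depended on the processing: adjusted p ranged from 0.00623 in limma-voom on the recovered reads to 0.177 without Bgal replicate 1.

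Among 17 tested ferroptosis drivers, 1 rose and 6 fell, with the same counts adjusted over the list alone. Lpcat3, which loads polyunsaturated fatty acids into phospholipids, fell from 93.3 ± 2.24 to 62.4 ± 0.247 FPKM. Vdac2 and Vdac3, channels of the outer mitochondrial membrane, fell 1.34-fold and 1.28-fold. Acsl4, which activates polyunsaturated fatty acids, stood at 17.2 ± 1.48 and 16.4 ± 1.65 FPKM and did not pass (95% confidence interval of the log2 difference -0.27 to 0.15, limma adjusted p = 0.62). The list did not pass in camera (adjusted p = 0.634). Hmox1, a heme-degrading enzyme, fell from 176 ± 37.1 to 89.4 ± 16.3 FPKM (limma adjusted p = 0.00528), and Ptgs2, a prostaglandin synthase, was the only member that rose, from 2.01 ± 0.191 to 3.91 ± 0.950 FPKM (limma adjusted p = 0.00941), both chosen here after their values were seen.

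Fth1, the ferritin heavy chain gene, was listed at 0 in every library. Gpx4, the lipid peroxide reductase, had 0, 0 and 1 reads in the Bgal libraries and 6, 1 and 3 in the Trim28 libraries. Slc40a1, the iron exporter, had 2 reads in Bgal replicate 3 and 0 elsewhere. Fth1 and Gpx4 are used by nearly all cells, so these values say only how the genes are listed, and none of the 3 was tested. A further entry described as solute carrier family 40, NEWGENE_620180, was chosen after its values were seen. It stood at 3.36 ± 0.564 and 3.08 ± 0.150 FPKM and did not pass (limma adjusted p = 0.562).

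**Figure D1:**
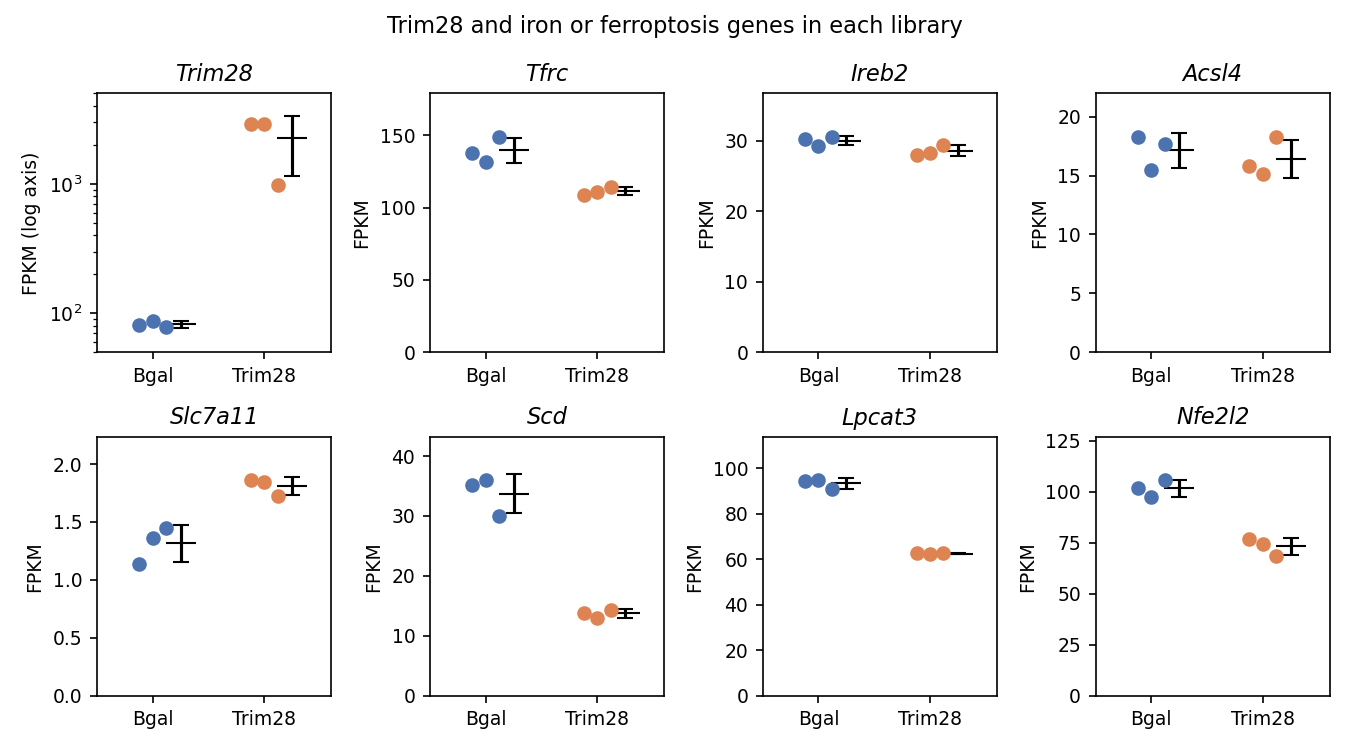
Each panel plots FPKM of 1 gene in the 3 Bgal and the 3 Trim28 libraries, with points for libraries, bars for the mean and SD, and a log axis for Trim28 only. Tfrc, Scd, Lpcat3 and Nfe2l2 lay lower in every Trim28 library, while Ireb2, Acsl4 and Slc7a11 did not pass the test. Slc7a11 nevertheless lay higher in every Trim28 library than in any Bgal library.

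Targets of NRF2 were split, with 4 of 18 higher and 7 lower, or 6 and 8 adjusted over the list alone. Prdx1, a peroxidase, fell from 317 ± 14.8 to 208 ± 3.68 FPKM. Gclc, the catalytic partner of Gclm, rose from 28.2 ± 1.38 to 41.5 ± 4.55 FPKM. Camera gave an adjusted p of 0.708 for the list.

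Over all 14808 tested genes, 2971 rose and 3126 fell, 41.2% in all, and most changes were small. At least a 2-fold change on the log2(FPKM + 1) scale was reached by 244 of the genes that rose and 172 of those that fell. The median log2 change of all tested genes was -0.02. After Trim28, the largest rises on that scale among genes that met the naming rule were those of Tppp3, a tubulin polymerisation protein, from 2.04 ± 0.205 to 30.7 ± 8.71 FPKM, and of Rfx2, a transcription factor of ciliary genes, from 0.884 ± 0.282 to 12.04 ± 0.450 FPKM. C2cd4b rose 6.85-fold, Lypd1 5.61-fold, Slc4a11 5.38-fold, the imprinted gene Dlk1 5.39-fold, and the protease inhibitor gene Slpi 5.78-fold. Their limma adjusted p-values lay between 1.42e-05 for Dlk1 and 0.00242 for Slpi.

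On the log2(FPKM + 1) scale, the largest falls under the same rule were led by ATP8, a mitochondrially encoded subunit of ATP synthase (chromosome MT, 7758 to 7961), from 335 ± 62.7 to 27.8 ± 0.582 FPKM. Dpm3, a subunit of a mannose transferase of the endoplasmic reticulum, fell from 16.2 ± 2.09 to 1.21 ± 0.871 FPKM. Reg3b, a secreted lectin, fell from 235 ± 24.5 to 49.2 ± 5.10 FPKM, and Myom2, a protein of the sarcomere M-band, from 128 ± 17.2 to 29.6 ± 3.71 FPKM. B3gat1, a glucuronosyltransferase, went from 5.19 ± 0.521 to 0.161 ± 0.0816 FPKM, and Tuba1c, which shares sequence with other alpha-tubulin genes and is therefore uncertain, from 17.3 ± 4.45 to 2.38 ± 0.343 FPKM. The ribosomal protein gene Rps19 (183 ± 168 to 25.6 ± 12.99 FPKM) shares its description with other entries for protein S19, which were not compared by sequence, and is uncertain, as its Bgal values of 77.4, 377 and 95.8 FPKM differed widely. The entry for Mir34a, the gene of a short regulatory RNA, fell from 6.64 ± 1.62 to 0.703 ± 1.22 FPKM on a length of 102 bases. Its values in the Trim28 libraries were 2.11, 0 and 0 FPKM. Adjusted p-values of these 8 genes in limma ranged from 1.42e-05 for ATP8 to 0.0134 for Rps19.

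Fibroblast and matrix genes rose together. Of 20 tested, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone, with a median log2 change of 0.65. Pdgfra, a growth factor receptor of fibroblasts, rose from 10.4 ± 0.144 to 28.8 ± 1.69 FPKM, and Col1a1, a chain of type I collagen, from 192 ± 14.4 to 388 ± 7.55 FPKM. Mmp2, a matrix protease, and Dcn, a matrix proteoglycan, rose 2.08-fold and 2.23-fold. The list passed in camera (adjusted p = 8.53e-10) but not with an estimated correlation (adjusted p = 0.161 with an estimated correlation).

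The lists of mural cell and leukocyte markers moved the same way. Other cells may also express some of these genes. Of 12 tested smooth muscle and mural genes 11 rose and 0 fell, also adjusted over the list alone, with a median log2 change of 0.55 (camera adjusted p = 5.64e-06, adjusted p = 0.285 with an estimated correlation). Kcnj8, at 0.403 ± 0.059 and 0.935 ± 0.068 FPKM, passed the filter through the Trim28 libraries alone. Pdgfrb, a receptor of pericytes, rose from 18.5 ± 1.43 to 37.0 ± 0.634 FPKM, and Acta2, smooth muscle actin, from 692 ± 111 to 1342 ± 52.1 FPKM. Of 15 leukocyte and macrophage markers 9 were tested and all 9 rose, also adjusted over the list alone, with a median of 0.82 (camera adjusted p = 2.97e-06, adjusted p = 0.135 with an estimated correlation). Lyz2, the macrophage lysozyme, rose from 13.8 ± 0.728 to 35.2 ± 0.716 FPKM, and the receptor gene Csf1r from 1.83 ± 0.202 to 4.54 ± 0.347 FPKM. Adgre1, at 0.107 ± 0.0383 and 0.746 ± 0.185 FPKM, passed the filter through the Trim28 libraries alone, and without a filter 10 of 14 markers rose and 0 fell. Of 14 endothelial markers 6 were tested, of which 3 rose and 1 fell, also adjusted over the list alone, with a median log2 change of 0.39. Without a filter 3 of 12 rose and 1 fell, with a median of 0.046. Eng, an accessory receptor for TGF-beta, rose from 33.0 ± 3.86 to 82.3 ± 1.33 FPKM, and Kdr, a receptor for VEGF, fell from 8.07 ± 0.642 to 6.06 ± 0.276 FPKM. The endothelial list did not pass in camera (adjusted p = 0.0734), although it did without Trim28 replicate 1 (adjusted p = 0.0281, with a range up to 0.315 over the alternatives).

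Immune response genes rose in the same libraries as the leukocyte markers. Of 24 tested interferon response genes 17 rose and 0 fell, also adjusted over the list alone, with a median log2 change of 0.78 (camera adjusted p = 7.46e-06, adjusted p = 0.61 with an estimated correlation). Without a filter 13 of 25 rose and 0 fell. Cmpk2, at 0.285 ± 0.0628 and 0.672 ± 0.0807 FPKM, passed the filter through the Trim28 libraries alone. Ifi27 rose from 121 ± 2.00 to 333 ± 73.3 FPKM, and Bst2, a tether of enveloped viruses, from 3.32 ± 0.376 to 11.2 ± 3.60 FPKM. The mean log2 rise of this list was 0.94, 0.98 and 0.35 in Trim28 replicates 1, 2 and 3. Of 18 tested inflammatory genes 15 rose and 0 fell, also adjusted over the list alone, with a median of 0.63 (camera adjusted p = 5.64e-06, adjusted p = 0.161 with an estimated correlation). Without a filter 13 of 20 rose and 0 fell. Icam1, an adhesion molecule, rose from 17.6 ± 1.68 to 33.3 ± 0.966 FPKM, the chemokine gene Cxcl1 1.65-fold, and the NF-kappaB subunit genes Nfkb1 and Nfkb2 1.43-fold and 1.56-fold.

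**Figure D2:**
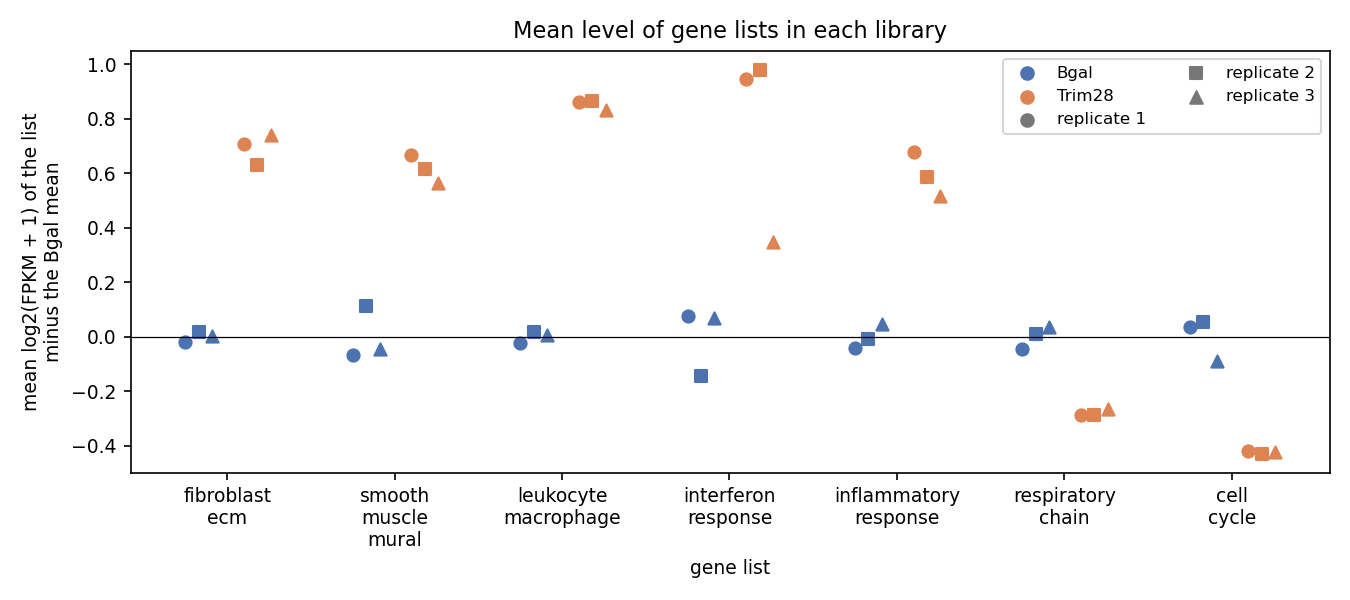
The plot gives the mean log2(FPKM + 1) of 7 gene lists in each library, minus the Bgal mean, with colours for groups and shapes for replicate numbers. The interferon list stood at 0.94 and 0.98 in Trim28 replicates 1 and 2 and at 0.35 in replicate 3, while the leukocyte list lay between 0.83 and 0.87 in these 3 libraries.

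Respiratory chain and cell cycle genes fell, in the libraries in which fibroblast, mural and leukocyte markers rose. Of 19 tested respiratory chain and ATP synthase genes 17 fell and 0 rose, or 18 and 0 adjusted over the list alone, with a median log2 change of -0.25 (camera adjusted p = 1.41e-05, adjusted p = 0.285 with an estimated correlation). Cycs, cytochrome c, fell from 579 ± 59.1 to 382 ± 7.12 FPKM, and Uqcrfs1, the iron-sulfur subunit of complex III, from 536 ± 24.2 to 388 ± 10.6 FPKM. Ndufa9 and Sdhb, of complexes I and II, fell 1.29-fold and 1.23-fold. Of 22 tested S phase and mitosis genes 16 fell and 0 rose, also adjusted over the list alone, with a median of -0.41 (camera adjusted p = 8.8e-06, adjusted p = 0.285 with an estimated correlation). Without a filter 12 of 22 fell and 0 rose. Birc5, survivin, fell from 4.14 ± 0.616 to 1.28 ± 0.207 FPKM, and the proliferation marker Mki67 from 4.73 ± 0.497 to 2.57 ± 0.261 FPKM.

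Part of the fatty acid oxidation genes fell, also in the libraries in which fibroblast, mural and leukocyte markers rose. Of 18 tested 9 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a median log2 change of -0.17 (camera adjusted p = 0.0322, adjusted p = 0.285 with an estimated correlation). Acsl1, which activates long-chain fatty acids, fell from 114 ± 7.12 to 58.6 ± 2.37 FPKM, and Fabp3, the heart fatty acid binding protein, from 920.3 ± 58.0 to 539.6 ± 28.4 FPKM. The call of this list was lost without Trim28 replicate 3 (adjusted p = 0.0584), with the replicate block (0.0521) and with the filter of 5 CPM (0.0588), within a range from 0.00363 over the alternatives.

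Heart muscle genes changed in both directions. Of 25 tested contractile genes 11 rose and 8 fell, also adjusted over the list alone, with a median log2 change of 0.01 (camera adjusted p = 0.708). Myl2 and Myl7, the ventricular and atrial regulatory light chains, fell from 1008 ± 219 to 362 ± 3.59 FPKM and from 41.1 ± 2.83 to 17.9 ± 1.95 FPKM. Tnni3, the adult cardiac troponin I, fell 1.65-fold. Among the members that rose were Actc1, from 5714 ± 859 to 9018 ± 164 FPKM, and Actn2, from 761 ± 20.2 to 1019 ± 14.8 FPKM. Myh6 stood at 3385 ± 93.1 and 3194 ± 37.3 FPKM and did not pass (limma adjusted p = 0.271). Actc1, Actn2 and Myh6 were chosen here after their values were seen. Of 15 tested genes of the fetal and stress program 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (median 0.26, camera adjusted p = 0.197). Fhl1, a LIM protein of stressed muscle, rose from 268 ± 54.7 to 845 ± 47.1 FPKM, Ccn2, a matricellular growth factor, from 87.8 ± 18.2 to 278 ± 49.6 FPKM, and the slow myosin gene Myh7 from 341 ± 56.3 to 752 ± 25.8 FPKM, while Myl4, the atrial essential light chain, fell 2.06-fold.

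The remaining stress, metabolic and chromatin lists did not pass in camera. Of 15 tested p53 targets 8 fell and 2 rose, also adjusted over the list alone, at an adjusted p of 0.0527. Over the alternatives that value ranged from 0.00808 with no filter to 0.138 without Trim28 replicate 3. The list also passed without Bgal replicate 1 (0.0272), Bgal replicate 3 (0.0365) or Trim28 replicate 2 (0.0284), and in limma-voom on the recovered reads (0.0286). Cdkn1a, an inhibitor of the cell cycle, fell from 251 ± 29.1 to 162 ± 7.69 FPKM, and Plk2 rose 1.81-fold. Of 18 glycolysis and hypoxia genes 3 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.481), with Adm, a vasodilator peptide, up 3.11-fold and Vegfa, an endothelial growth factor, down 1.70-fold. Of 18 ATF4 targets 5 rose and 7 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.708), and Ddit3, a stress transcription factor, fell 2.02-fold. Endoplasmic reticulum stress genes gave 2 higher and 4 lower of 15, or 2 and 3 adjusted over the list alone (adjusted p = 0.906), with Dnajb9 down 1.42-fold. Heat shock genes gave 2 higher and 6 lower of 12, also adjusted over the list alone (adjusted p = 0.342), with the mitochondrial chaperonins Hspe1 and Hspd1 down 1.64-fold and 1.39-fold.

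Of 19 cholesterol synthesis genes 5 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.226). Insig1, a sterol sensor, fell from 83.9 ± 3.38 to 50.6 ± 0.927 FPKM, while Srebf2, the transcription factor of the pathway, rose 1.35-fold. Of 20 TRIM28 partners, Trim28 included, 5 rose and 2 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.708). The median of this list was -0.01 and its mean 0.26, the latter carried by Trim28 itself. Cbx5, the heterochromatin protein HP1 alpha, fell 1.44-fold, and the related Trim24 rose 1.81-fold. Of 17 imprinted genes 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.507). Dlk1 rose from 2.88 ± 0.142 to 15.5 ± 0.807 FPKM, Igf2r rose 1.35-fold, and Plagl1 and the growth inhibitor gene Cdkn1c fell 1.76-fold and 1.64-fold.

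**Figure D3:**
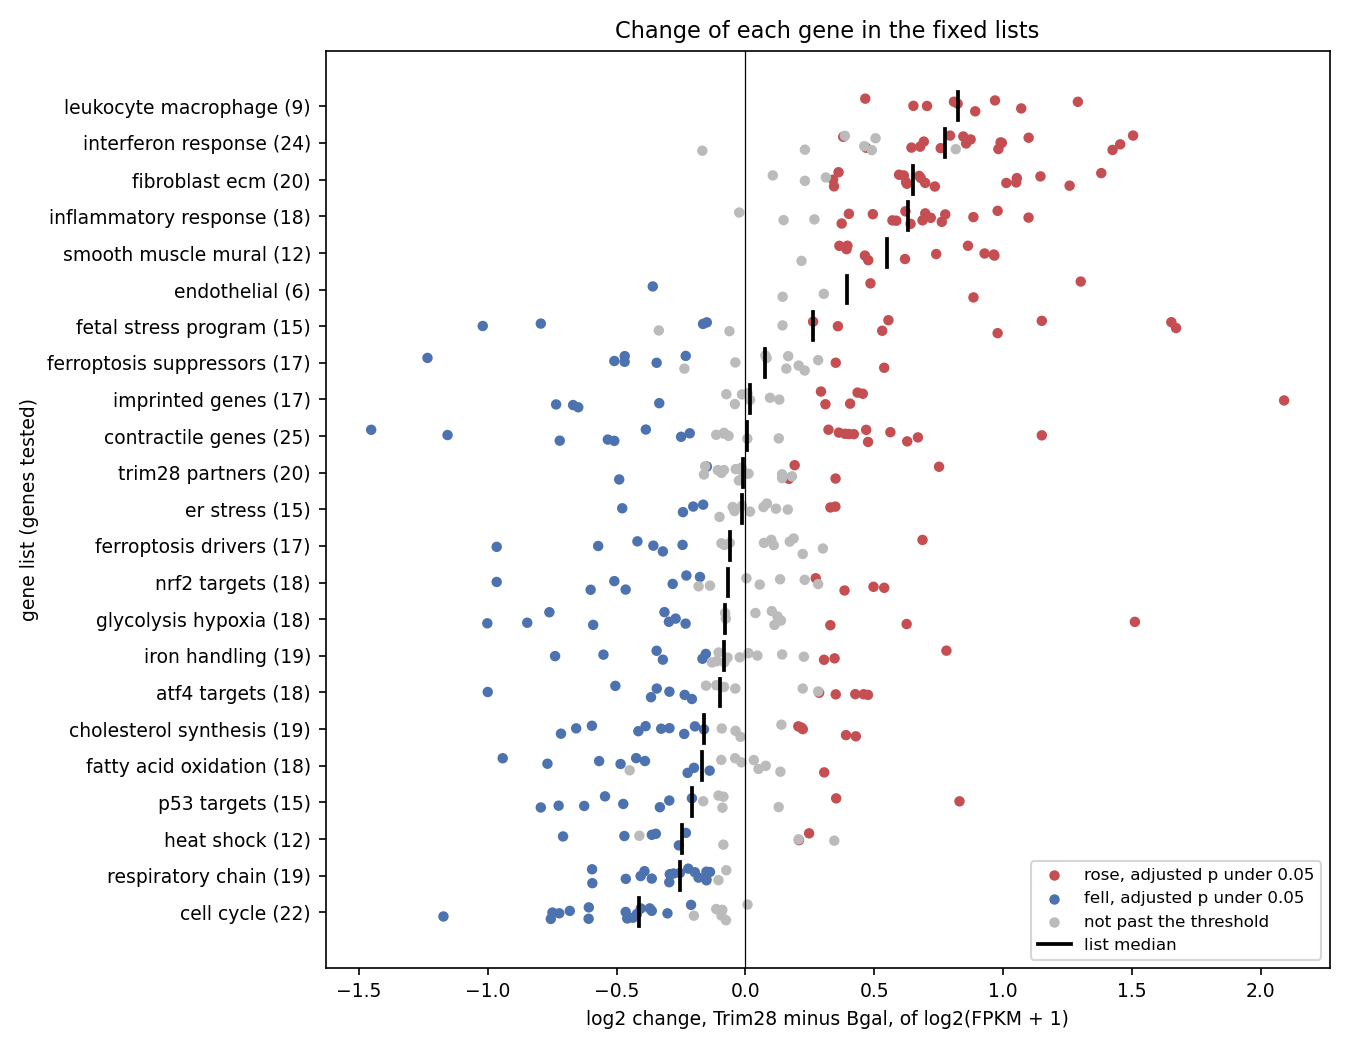
Each point is the log2 change (Trim28 minus Bgal, of log2(FPKM + 1)) of 1 tested gene in the 23 lists, coloured by the limma call, with a black bar for the list median, and Trim28 itself is left out of the drawing. Leukocyte, interferon, fibroblast and inflammatory lists lie to the right, with medians from 0.63 to 0.82, and respiratory chain and cell cycle lists to the left, with medians of -0.25 and -0.41.

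In all, 8 of the 23 lists passed in camera with the preset correlation. With an estimated correlation 0 passed after adjustment, 3 had an unadjusted p under 0.05, and fry, which asks whether a list moves on balance without comparing it with other genes, called 18.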

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

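The limma-voom, gene length and protein-coding alternatives were chosen only after the results were seen. Across the alternative scalings, filters, pseudocount, block, left-out libraries and added fits, with the preset correlation kept, no named gene and no list past the threshold changed direction where it was tested, and 102 of 106 named genes other than Trim28 and 20 of 23 lists kept their call. The exceptions were Slc7a11, the endothelial, fatty acid oxidation and p53 lists, and Herpud1, Calr and Chd4, whose calls were lost without Bgal replicate 1 (adjusted p = 0.0524), without Trim28 replicate 1 (0.0584) or 2 (0.0554), and without Trim28 replicate 1 (0.0665), respectively. Requiring a 2-fold change left 244 genes higher and 172 lower, by construction. With an estimated correlation between genes all 8 lists lost their call and 0 passed, and with fry 18 did. The estimated correlations of the leukocyte and fatty acid oxidation lists, -0.111 and 0.00884, were below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these lists. Their unadjusted camera p nevertheless went from 2.58e-07 to 0.00586 and from 0.0112 to 0.0628, respectively. The preset and estimated forms of camera thus differ in more than the correlation. For any of the lists, a call lost with an estimated correlation does not by itself show that its genes were correlated. Leaving out each library in turn gave 2249 to 2645 genes higher, 2402 to 2928 lower, 7 to 9 lists, and a log2 change of Trim28 of 4.34 to 5.13. Limma-voom on the recovered reads called 6507 genes, of which 5833 were shared with the 6097 of the report in the same direction. Median-of-ratios scaling moved the share of higher calls to 51.1%.

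With the replicate number as a block, 2744 genes were higher and 2922 lower, and 5389 calls were shared. Whether the numbers pair the libraries stays open. The correlations of same-numbered deviations were -0.02, 0.13 and 0.01. That of replicate 2 was the highest of all pairs, while Trim28 replicate 1 correlated best with Bgal replicate 3 (0.08). The block ended the call of the fatty acid oxidation list and changed no other named call.

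Over the 10 splits of the 6 libraries into equal groups, the real one gave 6097 genes and the highest other 1. For lists the real split gave 8, and the others gave from 2 to 7. Camera with the preset correlation thus called lists in every mixed split, although at most 1 gene passed there. In each case 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05.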

Other observations

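The tests on gene length, ATP8, Rps19, mitochondrial genes, fibroblast genes and Trim28 replicate 3 were chosen only after the results were seen, as were the family members named here, while the test of the C2H2 zinc finger family was written before its result was seen.

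Of 13 transcription factor families marked in the deposited table and tested, only those described here passed in camera with the preset correlation, and none of the 13 passed with an estimated one. Of 10 tested members of the Rel homology family 8 rose and 1 fell (median log2 change 0.54, camera adjusted p = 0.0158 over 13 families, adjusted p = 0.181 with an estimated correlation). Beside Nfkb1, Nfkb2 and Relb, which the inflammatory list also holds, Nfatc1 rose from 1.43 to 3.69 FPKM. Of 17 ETS genes 9 rose and 2 fell (adjusted p = 0.0309, adjusted p = 0.2 with an estimated correlation), with Etv1 going from 4.63 to 10.7 FPKM and Ets1 from 5.99 to 10.5 FPKM. Of 36 bZIP genes 16 rose and 6 fell (adjusted p = 0.0309, adjusted p = 0.375 with an estimated correlation), with Mafk and Fosl2 higher and Ddit3 and Nfe2l2 lower. TRIM28 works with some C2H2 zinc finger proteins, and the hypothesis of a common shift of that family was tested. The test took all tested genes that the deposited table marks so, and did not single out those that work with TRIM28. Of 397 genes 44 rose and 100 fell, with a median of -0.13 (camera adjusted p = 0.0309, adjusted p = 0.181 with an estimated correlation), so a common shift stays open. Zfp629 and Zkscan3 fell while Klf4 and Klf5 rose.

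Of 13 mitochondrially encoded protein genes, 9 fell, COX1 rose from 15235 to 19935 FPKM, and 3 did not pass. Mitochondrial genes took 7.10% to 8.14% of gene reads in the Bgal libraries and 6.65% to 6.73% in the Trim28 libraries.

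The largest falls included short genes, ATP8, Dpm3 and Rps19. After each library's trend with gene length was removed, the median log2 change of these genes was still -2.95. This argues only against a smooth trend over all tested genes as the whole cause. The removal moved ATP8 only from -3.53 to -3.45. A curve fitted over all tested genes cannot follow a loss confined to the shortest ones, so such a loss was not tested. The overlapping ATP6 also fell (log2 change -0.56, limma adjusted p = 0.00375). ATP8 fell by more, with a difference of -2.97 (SE 0.0837), which argues against a lower shared transcript as the whole cause only. Loss of reads on short genes within the compact mitochondrial genome is a candidate explanation, as the log2 change rose with length across the 13 genes (Spearman rho 0.692, permutation p = 0.0108, rho 0.608 without ATP8), although genes of 1 genome are not independent. For Rps19, a split of reads with other entries described as protein S19, which were not compared by sequence, may account for the fall, as the summed FPKM of 4 such entries was at least the lowest Bgal sum in 3 of 3 Trim28 libraries. A biological change of ATP8 or Dpm3 with the Trim28 group stays open and untested.

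The rise of fibroblast and matrix genes could come from a larger share of fibroblasts or from altered expression in the cells present. A share that multiplies all fibroblast genes by 1 common factor is argued against, because 5 of 8 fibroblast-restricted genes had an interval that left out the mean of the other 7, from 0.22 for Postn to 1.45 for Pdgfra on the log2 scale of reads. Sparc, an abundant member that other cells also express, rose from 767 to 986 FPKM, and Fn1 stood at 245 and 263 FPKM and did not pass. Gene length is argued against too, since the list's median was 0.63 after the trend was removed. Unequal folds do not exclude a change in cell share, since other cells may also express these genes. A change in cell share, in expression or in both with the Trim28 group stays open.

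The interferon list rose less in Trim28 replicate 3, by a difference of -0.61 on the log2 scale from the other 2 Trim28 libraries. A smaller share of leukocytes in that library is argued against, since the leukocyte list differed by only -0.033. Less virus or less transgene in replicate 3 may matter, as its Trim28 level was 0.337 of the mean of the other 2, but with 1 such library this cannot be told apart from other differences of that library. The fibroblast list differed by 0.071 and the inflammatory list by -0.11. The smaller rise was not confined to interferon genes. Tppp3, C2cd4b, Lypd1 and Slpi were also lower in replicate 3, as with Lypd1 at 37.3, 29.9 and 15.5 FPKM. Rfx2 differed little, and Slc4a11 and Dlk1 were not lowest there. Over all tested genes but Trim28, each library's log2 change had a slope on the mean change of the other 2. It was 0.894, 0.906 and 0.798 for Trim28 replicates 1, 2 and 3. All 3 changes were taken from the same Bgal means. Trim28 replicates 1 and 2 were also the most alike pair, with a chi-square per degree of freedom of 6.53, against 17 for each with replicate 3. The lower slope of replicate 3 therefore does not by itself show a smaller response over all genes.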
